A study of Homo sapiens with 5 samples.

How the data were processed

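Small RNA sequencing was analysed from 5 libraries of MCF10A, an immortalized, non-tumorigenic human mammary epithelial line. Per the labels, 3 libraries came from cells on uncoated plates (attached) and 2 from cells on plates coated with 2% poly-HEMA, a polymer to which cells do not adhere (detached). Per the labels, 50 µg of total RNA was extracted with TRIzol, and RNAs of 18 to 24 nt were size-selected and gel-purified before adapter ligation. The series' design text gives 24 h of culture for both groups, while the time label gives 0 h for the attached and 24 h for the detached libraries, so whether the attached cells were sampled at plating or after the same interval is unresolved. The labels do not say whether replicates were separate cultures, and p-values therefore measure only the spread between these libraries, which may be technical.

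The deposited count tables hold raw read counts, not normalized, for 49965 named small RNAs in each library, together with 5 summary rows of the counting program that total 0. The names cover mature miRNAs of many species, human piRNAs, snoRNAs, snRNAs and 5S rRNA copies. The 21014 rows for miRNAs of other species total 0 counts. The submitters' processing notes name genome build hg38 and DESeq2 without a role or version, and the aligner, the counter and the treatment of reads that match several names are not given in the sources used here. Near-identical mature sequences are therefore uncertain: miR-17-5p received 329 counts in all, and its close paralog miR-20a-5p 407388. The authors' deposited comparison table gives, per the file header, log2 fold changes with their standard errors, a test score, raw and adjusted p-values and, as signal, counts divided by library size factors, with their means per group. From those values 100% came out as whole reads within a tolerance of 0.01, and 100% of these equalled the raw counts. The size factors so recovered were 0.967, 0.704 and 0.969 for attached replicates 1, 2 and 3, and 1.32 and 1.34 for detached replicates 1 and 2.

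The tested features were the 2565 human miRNA rows, 15 of which join names with the same mature sequence, and library size was their total. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, quasi-likelihood F test, two-sided), after filterByExpr with a minimum count of 10 and a minimum total of 15, which kept 697 rows. Benjamini-Hochberg adjusted p under 0.05 counted as a call. Standard errors were obtained as the absolute log2 fold change divided by the square root of F. Levels are given as CPM, TMM-scaled counts per 1000000 human miRNA counts, and for other RNA classes as counts per 1000000 named counts, unscaled. The total of human miRNA counts ran from 8805009 to 15793173 per library, and a floor of 3 counts corresponds to 0.191 to 0.455 CPM. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

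The 16 miRNA lists were fixed before the data were examined. Of their 124 distinct members, 124 were matched and 103 passed the filter. The 15 lists with at least 3 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01, two-sided), again with an estimated correlation, and with fry. Named miRNAs followed a rule also fixed beforehand: called miRNAs with separated libraries by fold change, the 10 with the highest mean CPM, the 3 smallest p in each list, and the 5 smallest p per direction where fewer were called. Other members of the lists, the miRNAs called without attached replicate 2 or without the low-count filter and the RNAs outside the human miRNAs were named after their values were seen.

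Alternatives were DESeq2 1.42.0, limma-voom, other scalings, no filter and a stricter filter (100 CPM in 2 libraries), all named rows in place of human miRNAs, collapsing identical rows, a replicate block, a minimum change of 1.5-fold and leaving out each library. Voom with library quality weights, DESeq2 without attached replicate 2, reads recovered from the authors' values, the leave-one-out values of the top-10 share and an estimated correlation in the settings other than the main one were added after seeing the data. On counts simulated from all 5 libraries (662 rows run), the test recovered 35.1% of 4-fold, 57.1% of 8-fold and 85.7% of 16-fold changes, with 5 false among 109 calls. For the fit without attached replicate 2 (655 rows run) it recovered 72% of 4-fold, 98.0% of 8-fold and 100% of 16-fold changes, with 11 false among 181 calls. Simulated libraries shared the same dispersion for each miRNA, with no deviating library like attached replicate 2. The rates for all 5 libraries may therefore not hold for these data. Replicates of a group differed far beyond sampling noise (chi-square per degree of freedom 729 to 4220), so no library was treated as a duplicate.

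Hairpin positions, 1-based, and host genes come from GENCODE 29 on the hg38 assembly. Genomic clusters were hairpins on the same strand within 10000 bp, with mean CPM of at least 50. Hairpin sequences were compared with annotated snRNA, snoRNA, rRNA and other structured RNA transcripts through shared stretches of 18 nt. The 45S rRNA precursor was not used here. A GC offset was fitted per library by loess with span 0.75, on GC content known for 696 of 697 names. Hairpin GC here means the GC of the side of the hairpin, cut in the middle, that holds the named arm. For names without an arm it is the GC of the whole hairpin. Python 3.11.15, pandas 2.3.3 and scipy 1.17.1 were used.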

Results

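MCF10A cells, human mammary epithelial cells that normally grow attached, were profiled for small RNAs in attached culture (3 libraries) and after detachment on poly-HEMA (2 libraries). The comparison asks which miRNAs differ between adherent and suspended cells. Counts on all named small RNAs were 12366253, 8945953 and 10476182 in attached replicates 1, 2 and 3, and 16008489 and 10851744 in detached replicates 1 and 2. Human miRNAs held 98.3%, 98.4%, 98.5%, 98.7% and 97.1% of these in the same order. miR-21-5p, abundant in many cultured cells, held between 35.0% and 42.0% of human miRNA counts in every library, and miR-205-5p, a miRNA of basal and stratified epithelia, averaged 45723 ± 21153 CPM in attached (SD, n = 3) and 59372 ± 9417 CPM in detached cells (SD, n = 2).

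The 5 miRNAs with the smallest edgeR p toward higher levels in detached cells included miR-203a-5p and miR-145-5p. miR-203a promotes differentiation of stratified epithelium, and miR-145-5p is abundant in smooth muscle and described as p53-responsive. The other arm, miR-203a-3p, was not among these 5 and was named from the epithelial and keratinocyte list. miR-203a-3p measured 6.79, 9.26 and 6.37 CPM in the attached libraries and 122 and 38.4 CPM in the detached ones. miR-203a-5p had 2, 0 and 2 counts in attached and 113 and 107 in detached libraries. miR-145-5p averaged 0.736 ± 0.344 CPM in attached (SD, n = 3) and 11.6 ± 7.66 CPM in detached cells (SD, n = 2). With all 5 libraries, edgeR's quasi-likelihood test called 0 miRNAs higher at adjusted p under 0.05, with 33 higher at unadjusted p under 0.05. DESeq2 called 12 higher, limma-voom 0, voom with library quality weights 13, and edgeR without the low-count filter 14. The smallest edgeR adjusted p was 0.079, for miR-203a-5p (log2 fold change 5.79, SE 0.85), and miR-145-5p (3.98, SE 0.78) and miR-203a-3p (3.42, SE 0.73) had edgeR adjusted p of 0.146 and 0.170.

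The count moved with attached replicate 2. Its Spearman correlation with the other libraries across 697 miRNAs was 0.812 to 0.857, against 0.927 to 0.961 among the other 4. Leaving it out lowered edgeR's common biological coefficient of variation from 0.620 to 0.395 and gave 22 miRNAs higher and 1 lower, while leaving out any other library gave 0 and 0 (17 to 39 higher and 2 to 37 lower at unadjusted p under 0.05). Without a detached replicate, the other one was assumed to vary like the attached libraries. Attached replicate 2 deviated most in these same data, so leaving it out lowers the spread within the attached group by selection. The adjusted p of fits without it, here and below, may therefore be too small. In the fit without attached replicate 2, miR-203a-3p rose by a log2 fold change of 3.61 (SE 0.64, edgeR adjusted p 0.0033), miR-203a-5p by 5.40 (SE 0.68) and miR-145-5p by 4.15 (SE 0.71). miR-143-3p, which shares a primary transcript with miR-145, also rose (3.12, SE 0.71, edgeR adjusted p 0.0225, against 1.86, SE 1.00, with all 5 libraries), although attached replicate 2 held 14.1 CPM against 39.7 and 7.38 CPM in the detached libraries. With the GC offset miR-143-3p was no longer called (3.14, SE 0.74, edgeR adjusted p 0.0538). All 12 of the DESeq2 calls and all 13 of the quality-weight calls were among the 23 called without attached replicate 2. The quality weights gave attached replicate 2 a weight of 0.202, against 1.28 to 1.58 for the other libraries. That fit thus nearly left the library out, so its overlap is no separate evidence. The MIR203A hairpin lies on chromosome 14 from 104117405 to 104117514, outside annotated genes of types other than miRNA. Overlap with other miRNA genes was not searched. MIR143 (chromosome 5, 149428918 to 149429023) overlaps an exon and MIR145 (149430646 to 149430733) an intron of the long noncoding RNA CARMN.

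**Figure D1:**
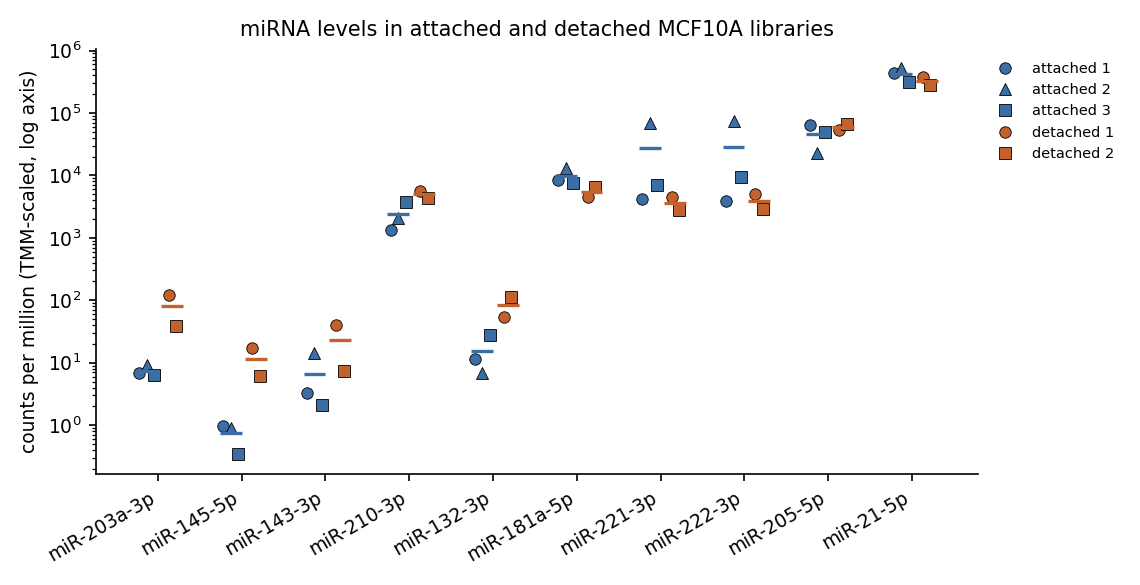
Level of 10 miRNAs in each library, in TMM-scaled CPM on a log axis, with horizontal lines at the group means (attached blue, n = 3; detached orange, n = 2). Both detached libraries lie above all attached ones for miR-203a-3p (122 and 38.4 CPM), miR-145-5p, miR-210-3p and miR-132-3p, and attached replicate 2, the triangle, carries the high miR-221-3p and miR-222-3p.

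Several other names that rose without attached replicate 2 were scarce or belong to less characterised miRNAs. miR-4417 rose most among those seen in every library, by 6.30 (SE 0.66, against 3.96 with all 5 libraries), from 5 counts each in attached replicates 1 and 3 to 410 and 574 counts in the detached libraries, with 40 counts in attached replicate 2. miR-1246, which shares sequence with U2 snRNA, rose by 5.08 (SE 0.60, against 1.51 with all 5), from 3.66 and 5.95 CPM to 158 and 170 CPM, but attached replicate 2 held 163 CPM. miR-6510-3p, from a hairpin that overlaps an exon of the keratin gene KRT15 (chromosome 17, 41517164 to 41517217), rose by 3.67 (SE 0.60, against 3.06 with all 5), with 3.34 CPM in attached replicate 2 and 0.784 and 1.70 CPM in the other attached libraries. miR-934, from an intron of VGLL1, rose by 4.09 (SE 0.66, against 2.74 with all 5), with 2.88 CPM in attached replicate 2 and 0.523 and 0.425 CPM in the others. miR-663a had 2 counts in each attached library and 43 and 58 in the detached ones. miR-3178 had 0 counts in all 3 attached libraries, where the floor is at most 0.455 CPM, and 18 and 17 counts in the detached ones. miR-6751-3p had 2, 0 and 1 counts in attached and 27 and 47 in detached libraries. miR-17-5p rose by 2.37 (SE 0.62), but it is uncertain, since its reads are hard to part from those of its paralogs and it held 11.2 CPM at most.

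Toward lower levels in detached cells, edgeR called 0 miRNAs with all 5 libraries, with 16 lower at unadjusted p under 0.05, and DESeq2, limma-voom and voom with quality weights each called 0. Without the low-count filter edgeR called 5 lower: miR-186-5p (-4.21, edgeR adjusted p 0.00105), miR-221-3p and miR-222-3p (0.0349 each), miR-4655-3p and miR-219b-3p. miR-186-5p measured 13121 CPM in attached replicate 2 against 197 to 362 CPM in the other 4 libraries, and without that library its log2 fold change was -0.69 (SE 0.48). In the filtered edgeR fit of all 5 libraries the smallest p belonged to miR-376a-5p, miR-181d-5p, miR-6793-5p, miR-181b-3p and miR-1287-5p, none of which passed there. DESeq2 without attached replicate 2 called miR-181b-3p lower (-1.92, adjusted p 0.0491). miR-181b-3p averaged 12.3 ± 3.03 CPM in attached (SD, n = 3) and 3.31 ± 1.45 CPM in detached cells (SD, n = 2), a log2 fold change of -1.89 (SE 0.67, edgeR adjusted p 0.531), and miR-376a-5p gave -2.40 (SE 0.72) and miR-1287-5p -2.08 (SE 0.74). miR-181d-5p and miR-6793-5p were highest in attached replicate 2, at 52.8 and 3.95 CPM. Without attached replicate 2, miR-548d-5p fell by 2.79 on the log2 scale (SE 0.57, edgeR adjusted p 0.00862), from 19.0 and 13.9 CPM to 1.59 and 3.20 CPM, but attached replicate 2 held 2.43 CPM.

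Among the 16 fixed lists, 1 passed the set test: the list linked to YAP and TEAD or to actin and SRF was higher in detached cells as a set. camera gave an adjusted p of 0.0124, and an adjusted p of 0.803 with an estimated correlation, while fry gave 0.446. Of its 7 tested members 6 had positive log2 fold changes, with a median of 1.65, led by miR-145-5p, miR-1-3p, miR-143-3p and miR-301a-3p. miR-145-5p and miR-143-3p also stand in the fibroblast and mesenchymal list and in the p53-responsive list. Here, as in every list, 0 members were called by edgeR over all miRNAs, with 1 higher at unadjusted p under 0.05, and 1 (miR-145-5p) adjusted over the list alone, a count that is 0 in the lists for which it is not given. Without attached replicate 2, camera's adjusted p was 0.0149, with an adjusted p of 0.931 with an estimated correlation, and 2 members, miR-143-3p and miR-145-5p, were called. The set call ended without attached replicate 3 and without detached replicate 1 (0 lists called in each). miR-1-3p, a muscle miRNA, reached 11.7 CPM in detached replicate 1 and 0.0761 CPM in detached replicate 2, so a single library sets its log2 fold change of 3.24 (SE 1.59).

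The 4 members of the miR-181 family, which tunes receptor signalling in lymphocytes, all had negative log2 fold changes, with a median of -0.96. camera gave an adjusted p of 0.0554, and an adjusted p of 0.803 with an estimated correlation. miR-181a-5p averaged 9761 ± 2993 CPM in attached (SD, n = 3) and 5508 ± 1360 CPM in detached cells (SD, n = 2), and miR-181b-5p 2715 ± 966 and 1347 ± 241 CPM. Set tests with the DESeq2 statistics and with no filter drew on 1918 rows with any count, against 697 in the main fit. The added rows had failed the low-count filter, so adjusted p from these 1918 rows do not compare directly with that of the main fit. With the preset correlation the family passed with the DESeq2 statistics (adjusted p 2.98e-04), limma-voom (0.014), quality weights (0.0456), no filter (0.0266), all named rows (0.0446), library totals (0.0455), without attached replicate 1 (0.0248) and without detached replicate 2 (0.0471). With an estimated correlation the adjusted p was 0.658 to 0.849 in these settings, DESeq2 aside, where none was estimated. It did not pass without attached replicate 2 (adjusted p 0.105, with 1 member, miR-181d-5p, lower adjusted over the list alone), without attached replicate 3 (0.106) or without detached replicate 1 (0.195).

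Basal mammary and MAPK-responsive miRNAs had 7 of 9 members negative and 2 lower at unadjusted p under 0.05, miR-221-3p and miR-222-3p (camera adjusted p 0.254, and an adjusted p of 0.803 with an estimated correlation). With the DESeq2 statistics, for which no correlation was estimated, the list passed as lower (adjusted p 0.0197), while fry on the edgeR fit gave an adjusted p of 0.342. The DESeq2 set test drew on the 1918 rows with any count, not on the 697 filtered ones. Leaving out attached replicate 2 gave 8 of 9 negative (camera adjusted p 0.105), with miR-221-3p at -0.61 (SE 0.49), miR-222-3p at -0.75 (SE 0.53) and miR-222-5p at -1.66 (SE 0.57). miR-221-3p and miR-222-3p were high in attached replicate 2 alone, at 69951 and 73861 CPM, against 2756 to 9415 CPM in the other 4 libraries. Their hairpins lie side by side on chromosome X, MIR221 from 45746157 to 45746266 and MIR222 from 45747015 to 45747124, in an intron of MIR222HG. miR-21-5p, in the same list, had a log2 fold change of -0.38 (SE 0.45), and miR-100-5p one of -0.73 (SE 0.49).

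The hypoxia-induced miR-210, with 2 arms tested and thus no set test, was higher in both detached libraries. miR-210-3p measured 1318, 2094 and 3800 CPM in attached and 5686 and 4425 CPM in detached libraries, a log2 fold change of 1.07 (SE 0.61, edgeR adjusted p 0.735), and miR-210-5p gave 2.44 (SE 0.92, edgeR adjusted p 0.577). 0 arms were called over all miRNAs by edgeR, with 1 at unadjusted p under 0.05, and 0 adjusted over the list alone. In the fit without attached replicate 2, miR-210-5p gave 1.93 (SE 0.52, edgeR adjusted p 0.0551), with 0 arms called over all miRNAs by edgeR, 1 at unadjusted p under 0.05 and 1 adjusted over the list alone, and DESeq2 called it (adjusted p 0.0138). MIR210 lies on chromosome 11 from 568089 to 568198, in an intron of MIR210HG.

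The lists of epithelial identity miRNAs did not pass the set test. In the miR-200 family, which maintains E-cadherin by repressing ZEB1 and ZEB2, 4 of 5 members were positive (camera adjusted p 0.706). miR-200c-3p gave 0.83 (SE 0.73), miR-200b-3p 1.01 (SE 0.68) and miR-141-3p -0.69 (SE 0.52). Without attached replicate 2 these were 0.37 (SE 0.46), 0.70 (SE 0.52) and -0.41 (SE 0.45), with 4 of 5 members positive (camera adjusted p 0.785). Of 9 tested epithelial and keratinocyte miRNAs 5 were positive (camera adjusted p 0.331). By edgeR 0 were called over all miRNAs, with 1 at unadjusted p under 0.05, and 1, miR-203a-3p, adjusted over the list alone. DESeq2 on all libraries called miR-203a-3p (adjusted p 0.00169), as did edgeR without the low-count filter (adjusted p 0.00567). The unfiltered edgeR fit also called miR-186-5p lower, a change carried by attached replicate 2 alone, so its calls are weak support. miR-224-5p gave 1.04 (SE 0.64), miR-96-5p 1.00 (SE 0.81) and miR-205-5p 0.38 (SE 0.56). Without attached replicate 2 these fell to 0.74 (SE 0.49), 0.53 (SE 0.49) and 0.05 (SE 0.45). Attached replicate 2 held 141 CPM of miR-96-5p, against 608 to 1299 CPM in the other libraries. In that fit 5 of 9 were positive (camera adjusted p 0.587), and edgeR called 1, miR-203a-3p.

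Lists tied to growth and stress had 0 members called by edgeR over all miRNAs. Of 9 let-7 family members, 6 were negative (camera adjusted p 0.457), with let-7i-5p at -0.77 (SE 0.63), let-7e-5p at -0.44 (SE 0.53) and let-7b-5p at -0.26 (SE 0.48). In the miR-17-92 and paralog clusters 8 of 11 were positive (camera adjusted p 0.357), yet miR-106b-5p (1.43, SE 1.04) and miR-25-3p (-2.92, SE 1.32), which share an intron of MCM7, had opposite signs. Without attached replicate 2, which held 6337 CPM of miR-25-3p, 5 of 11 were positive, with miR-106b-5p at 0.88 (SE 0.58) and miR-25-3p at -0.61 (SE 0.56). In the miR-15/16 family, which restrains cyclins and BCL2, 6 of 7 were positive (camera adjusted p 0.254), with miR-15b-5p at 1.94 (SE 0.94), miR-15a-5p at 1.74 (SE 0.92) and miR-503-5p at -0.47 (SE 0.65). Of 9 p53-responsive miRNAs 5 were positive (camera adjusted p 0.331), with 1 at unadjusted p under 0.05 and 1, miR-145-5p, adjusted over the list alone. In that list miR-34a-5p gave 0.14 (SE 0.55) and miR-107 1.53 (SE 1.03). Without attached replicate 2, 7 of 9 let-7 members were negative, with let-7i-5p at -0.30 (SE 0.48), 5 of 7 in the miR-15/16 family were positive, with miR-15b-5p at 1.40 (SE 0.47), and 6 of 9 p53-responsive miRNAs, with miR-107 at 0.98 (SE 0.51). In that fit edgeR called miR-145-5p and miR-143-3p of the p53-responsive list and miR-17-5p of its clusters. The p53-responsive list passed as higher without detached replicate 2 (camera adjusted p 0.0220, and an adjusted p of 0.502 with an estimated correlation), and the miR-15/16 family without attached replicate 1 (camera adjusted p 0.0382, and an adjusted p of 0.705 with an estimated correlation).

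Of 7 inflammation-linked miRNAs 2 were positive (camera adjusted p 0.902). miR-132-3p, a CREB target, measured 11.7, 6.83 and 28.0 CPM in attached and 55.0 and 114 CPM in detached libraries (log2 fold change 2.44, SE 0.79, edgeR adjusted p 0.497), and miR-146a-5p, an NF-kB target, gave -2.61 (SE 1.45) with 232 CPM in attached replicate 2. DESeq2 without attached replicate 2 called miR-132-3p higher (2.13, adjusted p 0.0160), while edgeR without that library gave 2.07 (SE 0.59, adjusted p 0.0708). Of 12 quiescence and extracellular-matrix miRNAs 5 were positive (camera adjusted p 0.644), with miR-29a-3p, a repressor of collagen mRNAs, at -1.28 (SE 0.73), miR-29b-3p at 0.33 (SE 0.58), miR-30b-5p at 1.00 (SE 0.60) and miR-30a-5p at -0.99 (SE 0.72). In the miR-23/27/24 clusters 4 of 5 were positive (camera adjusted p 0.783), with miR-24-3p at -2.10 (SE 1.09), miR-23b-3p at 0.69 (SE 0.58) and miR-27a-3p at 0.94 (SE 1.03). Without attached replicate 2, which held 6848 CPM of miR-24-3p against 640 to 834 CPM in the other 4 libraries, 3 of 7 inflammation-linked miRNAs were positive, with miR-146a-5p at -0.81 (SE 0.82), and 8 of 12 in the quiescence list, with miR-29a-3p at -0.38 (SE 0.47) and miR-30a-5p at -0.21 (SE 0.47). In the miR-23/27/24 clusters 3 of 5 were then positive, with miR-24-3p at -0.19 (SE 0.47) and miR-27a-3p at 0.38 (SE 0.47). In that fit camera's direction turned from down to up for the inflammation list (adjusted p 0.834; median -0.02, mean 0.23; 1 member, miR-132-3p, higher adjusted over the list alone) and the quiescence list (adjusted p 0.867). With all 5 libraries the miR-23/27/24 clusters had a median of 0.24, a mean of -0.01 and an upward camera direction.

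With all 5 libraries, none of the 3 lists of markers of other cells passed the set test, while the fibroblast and mesenchymal list passed as higher without detached replicate 2 (camera adjusted p 0.0220, and an adjusted p of 0.502 with an estimated correlation). In the fibroblast and mesenchymal list 3 of 4 tested members were positive (camera adjusted p 0.331). By edgeR 0 were called over all miRNAs, with 1 at unadjusted p under 0.05 and 1, miR-145-5p, adjusted over the list alone. DESeq2 on all libraries called miR-145-5p (adjusted p 0.00169), as did edgeR without the low-count filter (adjusted p 0.00220), where calls are weak support, as said above. Beside miR-145-5p and miR-143-3p, miR-152-3p gave 0.05 (SE 0.61) and miR-382-5p -1.95 (SE 0.86), while miR-214-3p, miR-10b-5p and miR-127-3p had 3, 6 and 0 counts over all libraries. In the blood and serum list 4 of 6 were positive (camera adjusted p 0.841), with miR-451a at 1.36 (SE 0.79), miR-142-3p at 0.37 (SE 0.85) and miR-126-5p at -1.14 (SE 0.65). In the neural and muscle list 1 of 5 was positive (camera adjusted p 0.600), with miR-129-5p at -1.46 (SE 0.95) and miR-138-5p at -0.56 (SE 0.59), a median of -0.27, a mean of 0.16 and a downward camera direction. Of the members tested without attached replicate 2, 2 of 4, 2 of 6 and 2 of 4 in these lists were positive, and both positive ones in the fibroblast and mesenchymal list, miR-145-5p and miR-143-3p, were called (list median 1.53). Among the others were miR-382-5p at -0.98 (SE 0.52), miR-142-3p at -0.11 (SE 0.52) and miR-451a at 0.90 (SE 0.51). For the blood and serum list, camera's direction turned from up to down in that fit (adjusted p 0.867; median -0.14, mean 0.02).

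**Figure D2:**
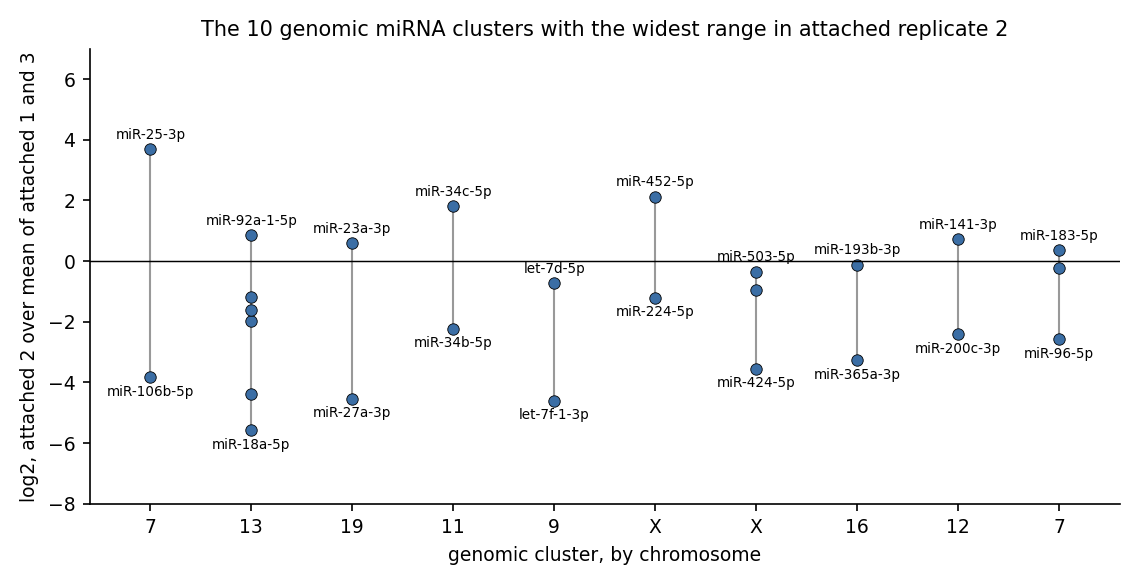
Log2 ratio of CPM in attached replicate 2 to the mean of attached replicates 1 and 3, for the members of the 10 genomic clusters with the widest range, each vertical line joining the members of a cluster (names mark the lowest and highest). Members of these clusters lie apart, as miR-25-3p at 3.69 and miR-106b-5p at -3.82, which follows in part from choosing the widest ranges. Some clusters not shown deviated together, as miR-221-3p at 3.66 and miR-222-3p at 3.47.

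The 10 miRNAs with the highest mean CPM over both groups held 70.1% ± 2.05 (SD, n = 3) of human miRNA counts in attached and 68.1% ± 4.54 (SD, n = 2) in detached cells, a difference of -2.01 percentage points (two-sided exact permutation p 0.5, where the smallest possible is 0.1). The difference in the share of human miRNA counts held by the 10 most abundant miRNAs, the same 10 kept, was 1.20 without detached replicate 2 and -5.22 without detached replicate 1. With the 10 chosen again, it was 1.20 without detached replicate 2, -5.87 without attached replicate 1 and -7.23 without attached replicate 3. Scaling by library totals alone moved the median log2 fold change of all miRNAs from -0.04 to 0.20. Of the other most abundant miRNAs, let-7a-5p gave a log2 fold change of -0.31 (SE 0.59), let-7f-5p 0.19 (SE 0.53) and miR-125b-5p -0.17 (SE 0.56).

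The authors' deposited table, a fit of the same libraries and so not independent, gives an adjusted p for 2991 of 44736 rows and lists 18 under 0.05. Of these 18, 8 higher and 1 lower in detached cells were piRNA names, and 5, all higher, were snoRNA, snRNA or other names. In the authors' deposited table, human miRNAs make up the other 4, all higher in detached cells: miR-203a-5p (log2 fold change 4.71), miR-145-5p (3.46), miR-203a-3p (3.10) and miR-4417 (3.39). All 4 were called in the edgeR fit without attached replicate 2 and by DESeq2, while edgeR on all 5 libraries shared 0 calls (it made none, with 33 higher and 16 lower at unadjusted p under 0.05). Across 693 miRNAs, which are not independent replicates, Spearman's rho of the log2 fold changes in the authors' deposited table and in edgeR was 0.997. The fold changes in the authors' deposited table lie nearer to 0 than the ratios of its group means for all rows with a mean above 100.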

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

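The test of 18-nt matches was chosen after its result was seen. The GC offset was set before.

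Small RNAs outside the human miRNAs were higher in both detached libraries for 5 of 14 classes, where a random split of the 5 libraries puts both on top in 10% of cases per class. The classes are not independent, since they share the composition of each library. Detached replicate 2 was the highest library in most classes and had the lowest human miRNA share (97.1%, against 98.3% to 98.7% in the others). The 10% is therefore no baseline for 5 of 14 classes. The mean count per 1000000 named counts, detached over attached, was 4.71 for 5S rRNA names, 5.66 for SCARNA names (small Cajal body RNAs), 1.99 for U1, 5.62 for U5 and 2.24 for U7 snRNA names. 5S rRNA names measured 51.8, 62.6 and 40.1 in attached and 157 and 328 in detached libraries. U5 names measured 38.3, 71.8 and 66.1 in attached and 92.8 and 567 in detached libraries, and U7 names 5.18, 5.48 and 5.63 in attached and 6.12 and 18.2 in detached libraries. With detached replicate 1 alone the ratios were 3.05 for 5S, 5.09 for SCARNA, 1.48 for U1, 1.58 for U5 and 1.13 for U7 names, so detached replicate 2 sets most of the U5 and U7 ratios. These class ratios were not tested. In edgeR fits of single names with all 5 libraries, 0 of 11 5S names were called (2 higher and 0 lower at unadjusted p under 0.05, median log2 fold change 0.06) and 0 of 56 snRNA names (7 higher and 2 lower, median 0.46). Without attached replicate 2, 0 of 10 5S names were called (2 higher and 0 lower at unadjusted p under 0.05, median 0.70). Of 54 snRNA names 2 were then called, both higher (9 higher and 1 lower at unadjusted p under 0.05, median 0.51).

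A candidate explanation for the miRNA names that rose without attached replicate 2 is that pieces of other structured RNAs were counted under miRNA names. Of 33 names whose hairpin shares 18 nt with such an RNA, 10 were higher at unadjusted p under 0.05, against 52 of 642 others (odds ratio 4.93, two-sided Fisher's exact p 0.000356). Names are not independent, since some are arms of the same hairpin, as for miR-15a, miR-1285 and miR-4485, which Fisher's test ignores. Among the 22 names called higher only miR-1246 and miR-1248 have such a match (odds ratio 2.01, Fisher's exact p 0.293), and with all 5 libraries the odds ratio was 1.23 (Fisher's exact p 0.679), so for the called names this stays open, also because 45S rRNA was not searched. After an offset on hairpin GC (of the side with the named arm, where the name gives an arm), 14 of the 22 names remained called. The median log2 fold change over all 22 was 3.61 (SD 1.28) before and 3.58 (SD 1.32) after. This argues against a bias that follows hairpin GC as the whole cause. A bias set by the GC of the sequenced mature miRNA was not tested, since the offset used hairpin GC. A part from GC stays open, as the called names had a median hairpin GC of 60.3% against 50.5% over all names. Spearman's rho of hairpin GC and fold change was 0.217 across names, which are not independent replicates. The 8 that lost the call had a median log2 fold change of 2.67 before and 2.54 after (median of the single names' SEs 0.66 before and 0.65 after). These 8 ended with adjusted p of 0.0538 to 0.147 by edgeR, having stood at 0.0225 to 0.0486 before. Among these 8 were miR-143-3p (edgeR adjusted p 0.0538) and miR-17-5p (0.0764). A response to detachment remains untested against these explanations.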

How the results depend on the processing

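Leaving out libraries was planned, while the quality weights, DESeq2 without attached replicate 2, the recovered reads, the leave-one-out top share and the estimated correlation in other settings were chosen after seeing the data. The counts of higher and lower miRNAs (0 and 0 by edgeR, 33 and 16 at unadjusted p under 0.05) became 12 and 0 by DESeq2, 14 and 5 without the low-count filter, 13 and 0 with quality weights, and 25 and 5 by DESeq2 without attached replicate 2. They ran from 0 to 22 and from 0 to 1 on leaving out each library, the highest of both without attached replicate 2, and stayed at 0 in the other scalings, limma-voom, the stricter filter, all named rows, recovered reads and the 1.5-fold test. Collapsing identical rows moved nothing. DESeq2 left 969 adjusted p as NA. With the replicate number as a block 0 and 0 were called and 0 lists. The correlation of deviations was -0.257 and -0.232 in the 2 pairs of like number. With 2 detached libraries, their deviations mirror each other, so these values cannot decide whether the numbers pair libraries. The number of lists called (1) was 2 under library totals, limma-voom, no filter, all named rows and quality weights, 3 with DESeq2, 0 with the stricter filter, an estimated correlation (also in each other setting where it was run) and fry, and 0 to 4 on leaving out each library (highest without detached replicate 2). The cause was not tested. The difference, detached minus attached in percentage points, in the share of human miRNA counts held by the 10 most abundant miRNAs was 0.473 for the 5 most abundant and, with the 10 chosen again from the remaining libraries, ran from -7.23 (without attached replicate 3) to 1.20 (without detached replicate 2), while the difference in the share of human miRNA counts held by the 10 most abundant miRNAs, the same 10 kept, ran from -5.22 (without detached replicate 1) to 1.20 (without detached replicate 2). Calls shared with the authors' deposited table were 1 at adjusted p under 0.1 and 4 with DESeq2. Of the alternatives for 57 named miRNAs 958 kept direction and side of the threshold, 29 passed it and 11 reversed. This tally does not count DESeq2 without attached replicate 2. Among the named miRNAs that passed there were miR-132-3p, higher (adjusted p 0.0160), and miR-181b-3p, lower (adjusted p 0.0491). Log2 fold changes that reversed on leaving out a library ran from -0.77 (without detached replicate 1) to 0.22 (without attached replicate 2) for hsa-let-7a-5p, which was also 0.17 without detached replicate 2, from -0.48 to 0.039 for hsa-let-7b-5p, from -0.18 to 0.77 for hsa-miR-29b-3p, from -0.29 to 0.63 for hsa-let-7f-5p, from -0.62 to 0.24 for hsa-miR-125b-5p and from -2.78 to 4.27 for hsa-miR-1-3p, in these 5 lowest without detached replicate 1 and highest without detached replicate 2, and from -0.11 (without attached replicate 2) to 1.01 (without attached replicate 3) for hsa-miR-142-3p. Quality weights gave 0.072 for hsa-let-7a-5p and -0.0066 for hsa-let-7f-5p, and the replicate block 0.024 for hsa-miR-125b-5p. Depth limits the scarce names: a change near 0.455 CPM is not detectable in attached replicate 2.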

Other observations

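The tests of clusters and of name families were chosen after attached replicate 2 was seen to stand apart. The test of depth was set before.

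In the fit of all named rows without attached replicate 2, edgeR called 6 of 442 other names higher and 0 lower (85 higher and 11 lower at unadjusted p under 0.05), and with all 5 libraries 0 of 462 (48 higher and 12 lower at unadjusted p under 0.05). DESeq2 was not run on these names here. U5E snRNA names rose by 4.45 (SE 0.54, edgeR adjusted p 0.0268), from 2.02 and 2.39 counts per 1000000 named counts to 37.8 and 77.6, and RNU4-78P, a U4 pseudogene copy, by 6.53 (SE 0.79). With all 5 libraries U5E gave 4.51 (SE 0.68, edgeR adjusted p 0.0568) and RNU4-78P 4.89 (SE 1.08, edgeR adjusted p 0.120). Attached replicate 2 held 1.56 counts per 1000000 of RNU4-78P, against 0.243 and 0.191 in the other attached libraries. The other 4 names called were piRNA names, hsa_piR_012510, hsa_piR_012670, hsa_piR_018980 and hsa_piR_020182. The authors' deposited table, over all libraries, lists RNU4-78P (log2 fold change 4.08) and SNORD49A (3.27) among its rows at adjusted p under 0.05.

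In attached replicate 2, 60 miRNAs with mean CPM of at least 50 differed over 4-fold from the mean of attached replicates 1 and 3 after centring on the median, 27 higher and 33 lower. miR-186-5p was 38.6-fold higher and miR-18a-5p was 47.5-fold higher in the mean of replicates 1 and 3. A different transcription of the hairpin clusters is argued against as the whole cause: within 21 clusters the SD of the log2 deviation was 2.09 in this library and 0.382 to 0.603 in the other 4. The SD over all miRNAs compared was also larger, 1.99 here and 0.646 to 0.822 in the other 4. The intraclass correlation of cluster members, which is free of this scale, was 0.126 (shuffle p 0.202). It was 0.117 to 0.545 in the other 4, so it does not single out the library. Lower depth is argued against too, since 10 miRNAs differed over 4-fold between attached replicates 1 and 3 thinned to its total. Sequence-dependent capture during library preparation may account for it: miRNAs of the same name family at different loci deviated together (intraclass correlation 0.547 over 18 families, shuffle p 0.0016, or 0.380 with clustered members kept), but the other 4 libraries gave 0.679 to 0.871 by the same measure, so this does not single out the library, and no biological explanation beyond transcription was tested.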
